A study of Mus musculus with 6 samples.

How the data were processed

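Single-cell RNA sequencing (10x Genomics 3' chemistry, version 3, per the labels' protocols) was performed on dissociated retinas of C57Bl/6J mice, an inbred laboratory strain, that were 10 weeks old. The retinas were taken 24 hours after an injection into the vitreous of either Staphylococcus aureus or phosphate-buffered saline (PBS). The series holds 6 libraries, 3 per group, and each group has 2 female libraries and 1 male library. Groups were taken from the treatment label of each sample, because 1 title misspells its group, and libraries are named here by group, sex and number. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

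Per the submitters' processing notes, the authors used Cell Ranger 7.2.0, Seurat 5 and the mouse genome build mm10. The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and cell, with no normalization. A deposited table of cells gives each cell's library, cluster, consensus cell type, doublet call and the percent of its UMIs that the authors assigned to mitochondrial genes. The cells kept by the authors have at least 501 UMIs, at least 301 genes and at most 14.9979% mitochondrial UMIs, and all are called singlets in the deposited table. The thresholds, the doublet caller and the references of the cell type calls are not given in the sources used here. Any step that removed free RNA from the counts is not given either. The matrices name 24541 gene symbols, of which 23929 have 1 position in GENCODE M21, the annotation from which coordinates are given (GRCm38, the build also called mm10). Of the genes on the lists below, 11 symbols are absent from the matrices. Whether the counting used the strand is not given in the sources used here, and reads of near-identical genes, such as Hspa1a with Hspa1b, or of overlapping genes, such as mt-Atp8 with mt-Atp6 and mt-Nd4l with mt-Nd4, may be split between them, so values of such genes are uncertain.

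The 47010 cells were used as deposited, with the authors' consensus cell types joined into 11 classes. Cells are not replicates, so UMIs were summed per library and class, and a class was tested where at least 2 libraries of each group held 20 cells of it. This left 6 classes: rods, cones, bipolar cells, amacrine cells, retinal ganglion cells and Muller glia. Genes with low counts were removed with edgeR's filterByExpr, and sums were scaled by trimmed mean of M values. Groups were compared with edgeR's quasi-likelihood test (robust estimates, no covariate), with Benjamini-Hochberg adjustment within a class and a threshold of 0.05. Fold changes are Bacteria over PBS, with standard errors (SE) from the same test, and levels are CPM, counts scaled to a fixed library total, as mean ± SD of 3 libraries per group. A gene with 0 counts in a group is given a lower bound of its fold, computed from the mean CPM of the other group and a floor of 3 counts over that group's libraries on the same scale. Intervals and floors cover counting error only.

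Fixed gene lists, 33 in number, were compared with the other genes of a class by limma's camera with a preset correlation of 0.01, with adjustment over the 123 tests of lists and classes with at least 5 tested members. The camera test with an estimated correlation and limma's fry were alternatives. Responses were compared between classes by the interaction of class and treatment in 1 model, with rods as the reference and each library as a block, and between sexes by the interaction of sex and treatment. Cell shares were tested with edgeR's quasi-likelihood test on cell numbers and, per class, with a two-sided exact permutation test, whose smallest p with 3 libraries against 3 is 0.1. Median UMIs and genes per cell were also compared after thinning each cell to 1000 UMIs.

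Named genes follow a rule: in rods and Muller glia the 12 largest rises and 8 largest falls, and elsewhere 5 and 3, among genes with an adjusted p under 0.05, a mean of at least 20 CPM and no overlap between the groups' libraries. Predicted, mitochondrial and ribosomal protein genes, and neutrophil or monocyte markers, were left out of this ranking. Up to 4 members with the smallest adjusted p were added for each called list. In classes too small for a test the 10 most abundant fixed markers were named. The text names part of these genes, with preference for those whose call and size held without each library, and this part was chosen after their values were seen. Single-gene results of some genes that the rule names are not reported here. The groups, the tests, the 33 lists, the naming rule, the cell type markers and most alternatives were fixed before the data were examined.

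The authors' 35 clusters were checked for leading genes of another class, which showed markers of other cells in part of the rods and Muller glia. The 10 leading genes of cluster 1 held 4 globin genes and no rod marker, those of cluster 29 held Pecam1, an endothelial gene, and no rod marker, and those of cluster 27 held 4 genes of the retinal pigment epithelium (RPE). Rods and Muller glia are therefore given as classes and also by cluster number.

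Alternatives were DESeq2 size factors and DESeq2's test, no filter on low counts, sex as a covariate, female libraries alone, the replicate number as a block, stricter cells (at least 500 genes and under 10% mitochondrial UMIs), doublets left out, equal cells per library, at least 50 cells per library, a test against a fold of 1.5, subtraction of estimated free RNA, and each library left out in turn. Scrublet marked 5 of the 47010 cells as doublets, too few for the caller to have worked on these cells. Added after the data had been seen were fits of the named clusters, of thinned bipolar sums, and of 4 smaller classes with at least 5 cells per library. Called genes were also counted without those at 0 in a library that should hold at least 20 UMIs, with no new fit. Fits were tested on simulated data drawn from the real means and library sizes with 200 changed genes. Every gene of a class was drawn with the common dispersion of that class. For the difference between bipolar cells and rods a fixed dispersion and separate draws of the classes were used. The numbers recovered hold for these settings, and genes with their own spread may be recovered at other rates. Of 100 genes with a 4-fold change, 85 were recovered in rods, 94 in cones, 96 in bipolar cells, 92 in amacrine cells, 74 in retinal ganglion cells and 87 in Muller glia. Of 100 genes with a 2-fold change, the numbers recovered were 11, 58, 54, 44, 24 and 21 in the same order. For the difference between bipolar cells and rods, 29 of 100 genes with a 4-fold difference were recovered. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scanpy 1.11.5.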

Results

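Retinas were examined 24 hours after Staphylococcus aureus, a bacterium that causes infection inside the eye, or PBS had been injected into the vitreous. The title of the series asks how each retinal cell type responds to the infection. The 6 libraries held 47010 cells, with 8223, 10385 and 8186 cells in PBS male-1, female-1 and female-2 and 3175, 7885 and 9156 cells in Bacteria male-1, female-1 and female-2. Total UMIs in the same order were 20170645, 26536183, 20975599, 11470354, 16444184 and 29450545.

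Neutrophils, the white blood cells that arrive early in bacterial infection, were found in every Bacteria library and in no PBS library. They made up 3.87%, 8.23% and 20.7% of the cells of Bacteria male-1, female-1 and female-2, a mean of 10.9% ± 8.76 (SD, n = 3), against 0 of 8223, 10385 and 8186 cells in the PBS libraries. A count of 0 allows shares of up to 0.0365%, 0.0289% and 0.0366% there, so the mean share was at least 299-fold higher after bacteria (edgeR adjusted p = 0.000115), and at least 165-fold higher without Bacteria female-2. Retinal ganglion cells, the neurons whose axons form the optic nerve, were a smaller part of the captured cells after bacteria, and loss was not told apart from lower capture. Their share was 2.42% ± 0.693 in PBS and 0.578% ± 0.149 in Bacteria libraries (n = 3 each), with 632 against 114 cells (log2 fold change -2.07, edgeR adjusted p = 0.00588). Exact permutation tests gave p = 0.1 for both classes, the smallest value that 3 libraries against 3 allow, and also for amacrine cells and Muller glia.

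The shares of the other 9 classes did not pass edgeR's test. Rods, the photoreceptors of dim light, were 67.5% ± 4.84 of cells in PBS and 58.0% ± 11.2 in Bacteria libraries (edgeR adjusted p = 0.644). Bipolar cells, which pass photoreceptor signals on, were 12.96% ± 1.90 and 13.7% ± 4.07 (adjusted p = 0.858), and cones were 2.26% ± 0.599 and 2.94% ± 1.46 (adjusted p = 0.581). Amacrine cells, inhibitory neurons of the inner retina, were 11.04% ± 1.67 and 5.73% ± 2.02 (log2 fold change -0.94, adjusted p = 0.138). Without Bacteria female-1 that value was -1.27 and passed the test. Muller glia, the radial glia that span the retina, were 2.95% ± 0.262 and 6.95% ± 3.49 (log2 fold change 1.24, adjusted p = 0.101). They passed at 1.58 without Bacteria male-1. Vascular cells, at 0.165% ± 0.0258 and 0.323% ± 0.187 (adjusted p = 0.198), passed at 1.36 without Bacteria female-1. Horizontal cells (0.347% ± 0.0663 and 0.185% ± 0.144), astrocytes (0.149% ± 0.0372 and 0.363% ± 0.343) and macrophages and microglia (0.229% ± 0.154 and 0.321% ± 0.211) were rare in both groups. The log2 fold change of astrocytes, 1.32, was 0.04 without Bacteria female-2, which held 69 of their 85 Bacteria cells.

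**Figure D1:**
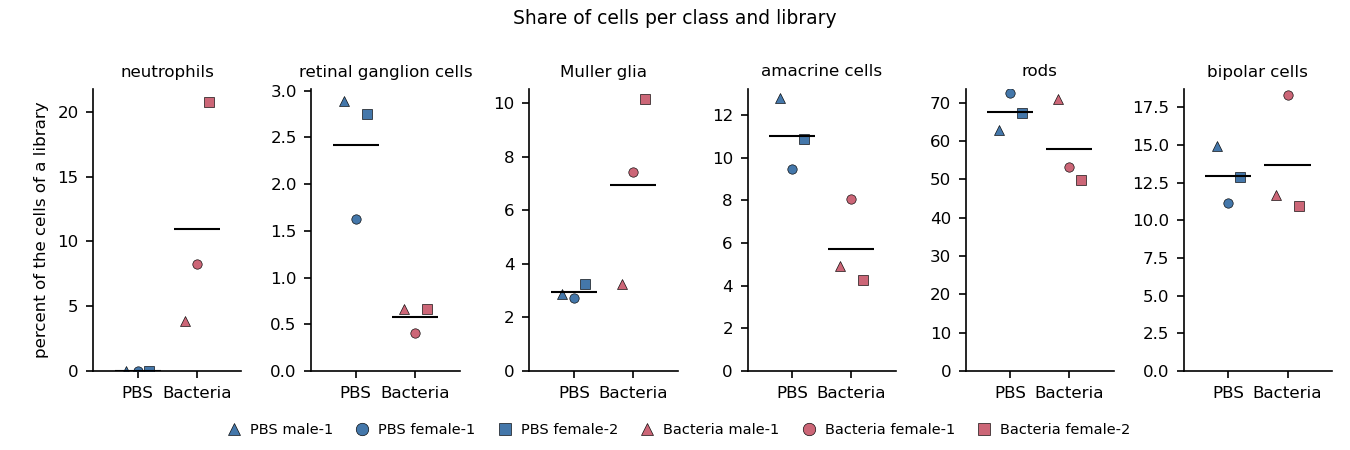
Percent of the cells of each library in 6 classes, on a linear axis that starts at 0, with PBS libraries in blue, Bacteria libraries in red, a triangle for the male library and a circle and a square for the female ones, and a line at the mean of 3 libraries. Neutrophils lie at 0 in PBS and between 3.87% and 20.7% after bacteria, and the mean of retinal ganglion cells is 2.42% against 0.578%.

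Genes of inflammation rose in Muller glia and genes of their support functions fell, and more genes changed in this class than in any other tested one. Ccl7, a chemokine that attracts monocytes (chromosome 11, 82045712 to 82047525), had no UMI in PBS and 771 ± 98.8 CPM after bacteria (n = 3 each), which is at least 2028-fold higher. Mmp12, a macrophage-type elastase, was likewise at 0 in PBS and at 478 ± 56.0 CPM after bacteria, at least 1256-fold higher. Kcnj10, the potassium channel by which Muller glia clear potassium (chromosome 1, 172341210 to 172374085), fell from 254 ± 21.4 to 4.64 ± 1.45 CPM (log2 fold change -5.61, SE 0.244, edgeR adjusted p = 7.41e-06). Of 12206 genes tested, 3780 rose and 4008 fell, of which 2979 and 3493 changed at least 2-fold. The groups' libraries did not overlap for 70.1% of genes, where chance gives 10%. The class rested on 785 cells in PBS and 1620 in Bacteria libraries, with 682329 to 5400137 UMIs per library.

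Nearly all tested cytokine and chemokine genes rose in Muller glia. Of 24 tested targets of NF-kB and cytokines 23 rose, 24 adjusted over the list alone (limma camera adjusted p = 3.48e-11, and adjusted p = 0.503 with an estimated correlation). Tnfaip3, a feedback inhibitor of NF-kB, rose by a log2 fold change of 8.62 (SE 0.379, adjusted p = 7.41e-06) from 1.94 ± 1.30 to 732 ± 31.5 CPM, and Zfp36 and Relb by 7.19 and 4.27. Of 9 chemokines 8 rose, 8 also adjusted over the list alone (adjusted p = 5.45e-05, and adjusted p = 0.503 with an estimated correlation). Cxcl2, which attracts neutrophils, reached 15833 ± 9433 CPM from 0 in PBS, at least 41652-fold higher. Its fitted log2 fold change of 18.24 was 17.64 without Bacteria female-2 and 18.86 without Bacteria male-1. Neutrophils themselves held 78616 CPM of Cxcl2, but only 4.98 CPM of Ccl7. All 8 tested genes of endothelial activation rose, 8 also adjusted over the list alone (adjusted p = 0.000189, and adjusted p = 0.503 with an estimated correlation). They include Vcam1, an adhesion molecule, at a log2 fold change of 1.77.

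Gliosis genes and signalling genes rose with them. Of 27 tested genes of reactive gliosis 26 rose, 26 also adjusted over the list alone (camera adjusted p = 2.19e-10, and adjusted p = 0.503 with an estimated correlation). Lif, a cytokine that photoreceptors respond to, rose from 4.11 ± 2.61 to 994 ± 185 CPM (log2 fold change 7.91, SE 0.489), and Ptx3 and Tgm1 by 7.87 and 8.66. Of 15 JAK-STAT3 genes 13 rose, 13 also adjusted over the list alone (adjusted p = 5.03e-05, and adjusted p = 0.512 with an estimated correlation), among them the kinases Pim1 (5.08) and Jak2 (2.30). Of 19 immediate early genes, which also respond to tissue dissociation, 17 rose, 17 also adjusted over the list alone (adjusted p = 2.72e-07, and adjusted p = 0.503 with an estimated correlation). Of 25 heat shock and unfolded protein response genes 19 rose and 1 fell, 20 and 1 adjusted over the list alone (adjusted p = 5.03e-05, and adjusted p = 0.705 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, rose by 3.53. Of 13 cell death genes 9 rose, 9 also adjusted over the list alone (adjusted p = 0.00563, and adjusted p = 0.503 with an estimated correlation). The named ones include Cflar (3.11) and Mdm2 (3.85), which restrain cell death and p53, and Tnfrsf10b (2.59), a death receptor. Of 12 disease-associated microglia genes 9 rose and 2 fell, 9 and 2 adjusted over the list alone (adjusted p = 0.0229, and adjusted p = 0.645 with an estimated correlation), with Axl, a receptor for dying cells, at 4.21 and Fabp5 at 4.96. The summed level of this list was lower, at 9322, 8637 and 8258 CPM in PBS male-1, female-1 and female-2. It was 4996, 4896 and 5870 CPM in the Bacteria libraries in that order. Of 26 genes of class I antigen presentation and interferon gamma 13 rose and 2 fell, 13 and 2 adjusted over the list alone (adjusted p = 0.0365, and adjusted p = 0.890 with an estimated correlation). That call was lost without PBS male-1 (adjusted p = 0.0685) and Bacteria male-1 (adjusted p = 0.231).

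Genes of glial support and of oxidative phosphorylation fell in Muller glia. Of 18 homeostatic Muller genes 13 fell and 2 rose, 13 and 2 adjusted over the list alone (camera adjusted p = 0.00180, and adjusted p = 0.6001 with an estimated correlation). Car14, a carbonic anhydrase, fell by 6.19 on the log2 scale, Lhx2, a transcription factor of retinal glia, fell by 3.62 and Prdx6, a peroxidase, fell by 2.53. Of 30 nuclear genes of oxidative phosphorylation 23 fell and 1 rose, 24 and 1 adjusted over the list alone (adjusted p = 0.000201, and adjusted p = 0.705 with an estimated correlation), with Ndufb10 at -3.41 and Atp5o at -3.09. Of 22 glycolysis genes 10 rose and 5 fell, 11 and 5 adjusted over the list alone, and camera did not call this list (adjusted p = 0.136), while fry, which asks whether a list moves one way, gave an adjusted p of 0.0055, higher. Nipal3, a magnesium transporter, fell by 7.09, and Lfng, which modifies Notch, was at 48.6 ± 7.97 CPM in PBS and 0 UMIs after bacteria, while neutrophils held 28.8 CPM. In the Muller sums of Bacteria male-1, female-1 and female-2, 103, 132 and 313 genes were at 0 where the lowest PBS level would give at least 20 UMIs, so a 0 of Lfng may not be its expression. The PBS sums held 119, 128 and 90 such genes by the lowest Bacteria level, and 3599 risen and 3582 fallen genes were left without those at 0 in some library. All 5 tested RPE genes fell, 5 also adjusted over the list alone (adjusted p = 0.0155, and adjusted p = 0.505 with an estimated correlation), such as Rgr at -6.46. These belong to the authors' cluster 27, whose leading genes were RPE genes. In cluster 5 alone, which holds 2260 of the 2405 Muller glia, 3755 genes rose and 3991 fell, 7577 genes were called in both fits, and 7576 of these had the same direction. With most cells shared, this agreement was largely built in. The 12 lists other than RPE genes kept their calls there, and RPE genes were too low to test. Kcnj10 was at -5.67 and Tnfaip3 at 8.67 in cluster 5. No left-out library moved the number of changed genes by over 1.5 times.

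**Figure D2:**
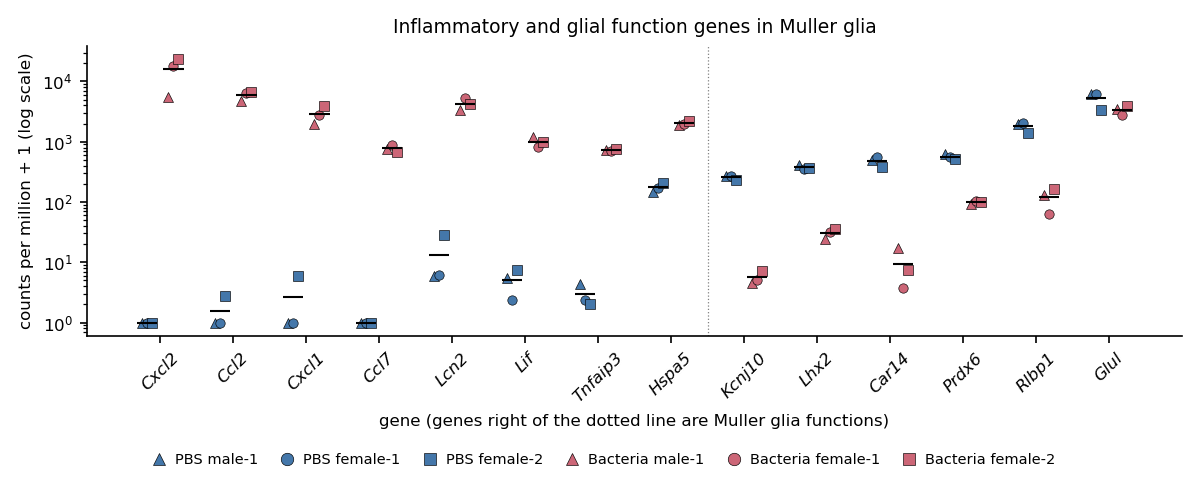
CPM plus 1, on a log axis, of 14 genes in Muller glia, 1 point per library and a line at the mean of 3 libraries, PBS in blue and Bacteria in red with a triangle for the male library. The chemokine and stress genes left of the dotted line lie higher after bacteria (Tnfaip3 at 1.94 against 732 CPM) and the glial genes right of it lower (Kcnj10 at 254 against 4.64 CPM), although Glul did not pass the test (edgeR adjusted p = 0.127).

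Interferon, JAK-STAT3 and early response genes rose in rods. Ache, acetylcholinesterase (chromosome 5, 137287519 to 137294466), rose from 1.14 ± 0.642 to 44.9 ± 25.8 CPM (log2 fold change 5.35, SE 0.658, edgeR adjusted p = 0.00408, n = 3 per group). BC046251, a transcript of unknown function (chromosome 7, 65582070 to 65618884), fell from 274 ± 24.2 to 55.1 ± 6.33 CPM (log2 fold change -2.32, SE 0.202, adjusted p = 0.00235), and Flrt3, an adhesion protein, fell by 2.14. In all, 977 genes rose and 636 fell among 12197 tested, 886 and 489 of them at least 2-fold. The groups' libraries did not overlap for 35.4% of genes, where chance gives 10%. The class held 18185 PBS and 11019 Bacteria cells, with 4740765 to 10623489 UMIs per library. The number of changed genes, 1613, was 684, 543 and 828 without PBS male-1, female-1 and female-2, and 3184 and 578 without Bacteria male-1 and female-1. Most rods of PBS libraries lay in clusters 0, 2 and 3 (39.9%, 20.9% and 19.9%), while clusters 1 and 6 held 15.03% and 0.357% in PBS against 26.7% and 19.9% after bacteria. In clusters 0, 2 and 3 alone 665 genes rose and 484 fell. Of the 1403 genes changed in the class that were tested in them, all had the same direction and 997 were called. The cells of these clusters are also part of the class, so such agreement was partly built in. In clusters 0, 1, 2 and 3 fitted separately, 1263 of 1273, 1346 of 1367, 607 of 678 and 602 of 644 such genes had the same direction. Those called in both fits numbered 1112, 1207, 344 and 352.

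Of 7 tested genes of the type I interferon response 5 rose in rods, 5 also adjusted over the list alone (camera adjusted p = 0.00175, and adjusted p = 0.674 with an estimated correlation). Irf9, a transcription factor of the interferon response, rose from 9.22 ± 4.60 to 103 ± 44.1 CPM (log2 fold change 3.49, SE 0.451, adjusted p = 0.00434), and was at 3.95 in clusters 0, 2 and 3. Bst2, an interferon-induced membrane protein that holds back viruses, rose by 3.84. Of 10 JAK-STAT3 genes 7 rose, and 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.00111, and adjusted p = 0.503 with an estimated correlation). Cish, a feedback inhibitor of cytokine receptors, rose by 3.42 and Il6st, the shared receptor chain of Lif and interleukin 6, by 2.29. Of 11 gliosis genes 9 rose and 1, Cd44, fell, 9 and 1 adjusted over the list alone (adjusted p = 4.52e-05, and adjusted p = 0.503 with an estimated correlation). Of 13 immediate early genes 8 rose, 9 adjusted over the list alone (adjusted p = 5.26e-06, and adjusted p = 0.503 with an estimated correlation). Fosb was at 3.81 and Junb at 4.56, with 414 ± 139 CPM in rods after bacteria beside 3627 CPM in neutrophils. Of 23 heat shock genes 10 rose, 11 adjusted over the list alone (adjusted p = 0.000670, and adjusted p = 0.705 with an estimated correlation), such as Hspa1a at 3.73 and Dnaja1 at 1.74. In clusters 0, 2 and 3 the members that rose numbered 5 of 6 interferon, 6 of 9 JAK-STAT3, 6 of 8 gliosis, 7 of 10 immediate early and 5 of 21 heat shock genes. Cluster 0 alone lost the calls of the interferon list (adjusted p = 0.162) and of the JAK-STAT3 list (adjusted p = 0.0748), and cluster 3 that of the JAK-STAT3 list (adjusted p = 0.533).

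Rod phototransduction genes, which turn light into a signal, were lower as a list. Their summed level was 134500, 112970 and 79533 CPM in PBS male-1, female-1 and female-2. It was 81492, 37050 and 31087 CPM in Bacteria male-1, female-1 and female-2, so Bacteria male-1 lay within the PBS range. Of 22 tested genes 2 fell and 0 rose, and 7 fell adjusted over the list alone (camera adjusted p = 4.95e-07, and adjusted p = 0.705 with an estimated correlation). These were Pde6b (log2 fold change -1.43, adjusted p = 0.0438) and Sag (-1.51, adjusted p = 0.0483). Both lost the call without each library other than Bacteria male-1, with adjusted p of 0.0921 to 0.194 for Pde6b and 0.105 to 0.210 for Sag. In clusters 0, 2 and 3 no member was called, while 13, 14, 4 and 15 fell in clusters 0, 1, 2 and 3 fitted separately. Of 22 glycolysis genes 3 rose, and 8 rose and 1 fell adjusted over the list alone (adjusted p = 0.0380, and adjusted p = 0.864 with an estimated correlation). That list lost its call without PBS female-1 (0.0891), PBS female-2 (0.278), Bacteria male-1 (0.572) and Bacteria female-1 (0.0594), and after free RNA was subtracted (0.0888). Pfkp, a phosphofructokinase, rose by 1.93. Nuclear genes of oxidative phosphorylation and ribosomal protein genes were lower as lists (adjusted p = 0.000192 and 3.56e-05, and adjusted p = 0.821 and 0.774 with an estimated correlation). In Bacteria male-1 their summed levels, 7807 and 18701 CPM, lay within the PBS ranges of 6596 to 11627 and 14259 to 26600 CPM. In Bacteria female-1 and female-2 they were lower, at 4417 and 2988 CPM for oxidative phosphorylation and 7367 and 3499 CPM for ribosomal protein genes. None of the 30 and 25 members was called, and none adjusted over the list alone, while edgeR put 3698 of all tested genes at an unadjusted p under 0.05. By cluster their direction differed. Oxidative phosphorylation genes were called higher as a list in cluster 1 (adjusted p = 0.000384), where 18 of 30 rose and 2 fell. That list pointed higher in cluster 0 without a call (adjusted p = 0.273), and in clusters 0, 2 and 3 together it was not called (adjusted p = 0.0885). Ribosomal protein genes pointed higher as a list in cluster 1 without a call (adjusted p = 0.322), and 6 of 24 rose and 1 fell there. In cluster 3 alone 22 of 25 fell and 0 rose, and in cluster 0 alone the list was not called (adjusted p = 0.983). Red blood cell genes were lower as a list (adjusted p = 0.0153, and adjusted p = 0.753 with an estimated correlation), with 1 of 6 fallen, 1 also adjusted over the list alone, and globin genes led cluster 1. They summed to 4591, 2052 and 5043 CPM in PBS male-1, female-1 and female-2 and 3829, 122 and 52.6 CPM in the Bacteria libraries in that order, so Bacteria male-1 lay within the PBS range. Alas2 (-1.28) lost its call without each library other than Bacteria male-1 (edgeR adjusted p of 0.0821 to 0.198). Of 7 genes of the bipolar ON pathway 2 rose, 2 also adjusted over the list alone (adjusted p = 0.0351, and adjusted p = 0.503 with an estimated correlation), a call lost without Bacteria male-1 (adjusted p = 0.0726) and without the rods of clusters 6, 28 and 36 (adjusted p = 0.0516), which come mostly from 1 group each.

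In the sums of cones, the photoreceptors of daylight, light-response and oxidative phosphorylation genes fell while Stat3 and heat shock genes rose. Stat3, a transcription factor activated by cytokines, rose from 56.7 ± 13.5 to 453 ± 45.5 CPM (log2 fold change 3.001, SE 0.229, edgeR adjusted p = 4.68e-06, n = 3 per group). Nr2e3, a photoreceptor transcription factor and a rod marker of the fixed lists (chromosome 9, 59942771 to 59960659), fell from 302 ± 56.0 to 55.8 ± 23.8 CPM (log2 fold change -2.36, SE 0.269, adjusted p = 7.33e-05). Whether this Nr2e3 came from cones or from rod RNA in their sums was not tested. In all, 852 genes rose and 665 fell among 9198 tested, 545 and 296 at least 2-fold, in 597 PBS and 517 Bacteria cells with 424110 to 1483973 UMIs per library. The groups' libraries did not overlap for 37.4% of genes, where chance gives 10%. The 1517 changed genes became 761, 802 and 911 without PBS male-1, female-1 and female-2. Estimated free RNA, which can carry other cells' transcripts, was 4.08%, 3.01% and 1.76% of cone UMIs in PBS male-1, female-1 and female-2. It was 59.5%, 48.2% and 17.5% in Bacteria male-1, female-1 and female-2, and 568 genes were called after its subtraction. The estimate divides the share of Muller glia markers in cones by their share in the library. Homeostatic Muller genes fell in Muller glia after bacteria, so the estimate may be too high there. In rods of the Bacteria libraries the estimate, made with the same library share, was 4.60%, 3.54% and 1.01% in the same order. A smaller library share would raise the estimates of rods and cones alike, so it does not account for the gap between them.

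Of 13 tested cone phototransduction genes 8 fell, and 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000639, and adjusted p = 0.6001 with an estimated correlation). Gngt2, the cone transducin gamma subunit, fell by 1.70 on the log2 scale and Kcnv2, a channel subunit of photoreceptors, fell by 1.22. After free RNA was subtracted this list lost its call (adjusted p = 0.526), as did Gngt2 (0.277) and Kcnv2 (0.0804). Of 22 rod phototransduction genes, several of which cones share, 14 fell, 18 adjusted over the list alone (adjusted p = 1.68e-10, and adjusted p = 0.6001 with an estimated correlation). They summed to 62847, 36874 and 45059 CPM in cones of PBS male-1, female-1 and female-2, and 19455, 22203 and 7851 CPM in the Bacteria libraries in that order. Cone phototransduction genes summed to 40711, 42076 and 41418 CPM in the PBS libraries and 28511, 14962 and 15701 CPM in the Bacteria libraries in that order. In PBS cones the rod genes thus reached levels like those of the cone genes. A fall of the rod list in cones was therefore not told apart from less rod RNA in their sums. The fall of the cone list was not told apart from more free RNA of other cells, since subtraction removed its call. Of 30 nuclear oxidative phosphorylation genes 15 fell, 23 adjusted over the list alone (adjusted p = 1.13e-09, and adjusted p = 0.674 with an estimated correlation), such as Cox5b at -1.43. Of 25 ribosomal protein genes 11 fell, 23 adjusted over the list alone (adjusted p = 2.07e-08, and adjusted p = 0.705 with an estimated correlation), and of 13 genes of mitochondrial DNA 3 fell, 3 also adjusted over the list alone (adjusted p = 0.000691, and adjusted p = 0.753 with an estimated correlation). Of 23 heat shock genes 10 rose, 11 adjusted over the list alone (adjusted p = 0.000191, and adjusted p = 0.505 with an estimated correlation), with Hsph1 at 2.63. Of 11 gliosis genes 7 rose, and 8 rose and 1 fell adjusted over the list alone (adjusted p = 5.60e-07, and adjusted p = 0.503 with an estimated correlation), with Fgf2, a survival factor, at 2.65. Of 10 immediate early genes 5 rose, 7 adjusted over the list alone (adjusted p = 1.96e-05, and adjusted p = 0.503 with an estimated correlation). Of 9 JAK-STAT3 genes 5 rose, and 5 rose and 1 fell adjusted over the list alone (adjusted p = 0.00145, and adjusted p = 0.645 with an estimated correlation), a call lost after free RNA was subtracted (adjusted p = 0.767). The bipolar ON pathway was called with 2 of 6 genes risen, 2 also adjusted over the list alone (adjusted p = 0.0372, and adjusted p = 0.503 with an estimated correlation), and lost without Bacteria female-1 (adjusted p = 0.0979).

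Bipolar cells had lower levels of nuclear oxidative phosphorylation, ribosomal and antioxidant genes after bacteria, and higher levels of the chaperone Hspa1a. Hspa1a (chromosome 17, 34969190 to 34972156) had no UMI in PBS and 152 ± 86.7 CPM after bacteria (n = 3 each), at least 808-fold higher in these counts. The bipolar sums of PBS male-1, female-1 and female-2 held 14, 19 and 7 genes at 0 where the lowest Bacteria level would give at least 20 UMIs. Rods and cones of PBS libraries held 71.7 and 37.3 CPM of Hspa1a, so its 0 in bipolar cells may not be its expression. Ifrd1, a regulator of stress-related transcription, fell from 47.3 ± 3.63 to 3.71 ± 1.45 CPM (log2 fold change -3.69, SE 0.266, edgeR adjusted p = 0.00106), although neutrophils held 1455 CPM of it. In all, 1962 genes rose and 1733 fell among 12929 tested, 716 and 912 at least 2-fold, in 3434 PBS and 2820 Bacteria cells with 2887560 to 6073198 UMIs per library. The groups' libraries did not overlap for 48.7% of genes, where chance gives 10%. The 3695 changed genes became 1613, 1408 and 1962 without PBS male-1, female-1 and female-2, and 5831 and 1997 without Bacteria male-1 and female-2.

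Of 30 nuclear oxidative phosphorylation genes 21 fell in bipolar cells, 27 adjusted over the list alone (camera adjusted p = 7.69e-09, and adjusted p = 0.674 with an estimated correlation). Ndufa4, a subunit linked to cytochrome oxidase (chromosome 6, 11900292 to 11907497), fell from 1127 ± 188 to 307 ± 88.9 CPM (log2 fold change -1.88, SE 0.234). Other energy lists were not called: of 13 genes of mitochondrial DNA 5 rose, 5 also adjusted over the list alone (adjusted p = 0.103), and of 22 glycolysis genes 4 rose and 1 fell, 4 and 1 adjusted over the list alone (adjusted p = 0.990). Of 25 ribosomal protein genes 12 fell, 20 adjusted over the list alone (adjusted p = 1.07e-05, and adjusted p = 0.757 with an estimated correlation). Their summed level was 11326, 12536 and 11319 CPM in PBS male-1, female-1 and female-2 and 9803, 4900 and 4903 CPM in Bacteria male-1, female-1 and female-2, so the fall lay mostly in the female libraries. Rplp0, Rps6, Rpl32 and Rpl37, which did not pass in the class, are among the genes called for the interaction of sex and treatment. Of 17 antioxidant and metal response genes 9 fell and 1 rose, 10 and 1 adjusted over the list alone (adjusted p = 0.00119, and adjusted p = 0.674 with an estimated correlation), with Gpx4, which reduces lipid peroxides, at -1.20. Of 9 targets of NF-kB 3 fell and 1, Bcl3, rose, 4 and 1 adjusted over the list alone (adjusted p = 0.0215, and adjusted p = 0.753 with an estimated correlation). Nfkbia, the inhibitor of NF-kB, had 119, 164 and 116 UMIs in PBS male-1, female-1 and female-2 and 0 in each Bacteria library, while neutrophils held 5616 CPM of it. In the bipolar sums of Bacteria male-1, female-1 and female-2, 9, 42 and 51 genes were at 0 where the lowest PBS level would give at least 20 UMIs, so a 0 of Nfkbia may not be its expression, and the call of the NF-kB list includes it. Of 9 homeostatic Muller genes 3 fell, 3 also adjusted over the list alone (adjusted p = 0.0155, and adjusted p = 0.705 with an estimated correlation), a call lost without PBS female-2 (adjusted p = 0.0948), and Rlbp1, a retinoid-binding protein of glia, was at 0 after bacteria, at least 15.1-fold lower. Of 7 disease-associated microglia genes 3 fell, 5 adjusted over the list alone (adjusted p = 0.0114, and adjusted p = 0.705 with an estimated correlation), a call lost after free RNA was subtracted (adjusted p = 0.0526).

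Amacrine cells had higher levels of chaperone genes and of mitochondrial DNA genes. Hsp90aa1, a chaperone, rose from 163 ± 21.7 to 786 ± 104 CPM (log2 fold change 2.27, SE 0.147, edgeR adjusted p = 0.000194, n = 3 per group). Stat3 rose by 2.30 and Synm, an intermediate filament protein, by 3.38. Dock2, a signalling protein of blood cells (chromosome 11, 34226815 to 34783892), was at 69.0 ± 7.17 CPM in PBS and 0 UMIs after bacteria, while neutrophils held 343 CPM. In the amacrine sums of Bacteria male-1, female-1 and female-2, 3, 19 and 63 genes were at 0 where the lowest PBS level would give at least 20 UMIs, so a 0 of Dock2 may not be its expression. In all, 1148 genes rose and 1383 fell among 13108 tested, 308 and 1025 at least 2-fold, in 2924 PBS and 1179 Bacteria cells with 888927 to 4504930 UMIs per library. The groups' libraries did not overlap for 39.8% of genes, where chance gives 10%. The 2531 changed genes became 1045, 838 and 762 without PBS male-1, female-1 and female-2, and 4372 and 1459 without Bacteria male-1 and female-1.

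Of 13 genes of mitochondrial DNA 8 rose in amacrine cells, 10 adjusted over the list alone (camera adjusted p = 1.70e-05, and adjusted p = 0.674 with an estimated correlation), with mt-Nd4l at a log2 fold change of 2.03. Of 20 heat shock genes 8 rose, 9 adjusted over the list alone (adjusted p = 6.95e-05, and adjusted p = 0.705 with an estimated correlation), a call lost without Bacteria male-1 (adjusted p = 0.109). Of 22 glycolysis genes 5 rose, 5 also adjusted over the list alone (adjusted p = 0.0439, and adjusted p = 0.821 with an estimated correlation), including the hexokinase Hk2 at 2.16. Its call was lost without PBS male-1 (0.154), PBS female-2 (0.0552) and Bacteria male-1 (0.572), after free RNA was subtracted (0.547) and with sex added (0.05505). Of 5 gliosis genes 2 rose, 3 adjusted over the list alone (adjusted p = 0.0144, and adjusted p = 0.505 with an estimated correlation), a call lost without each Bacteria library (male-1 0.574, female-1 0.599, female-2 0.190). Of 7 pattern recognition genes 3 fell, 4 adjusted over the list alone (adjusted p = 0.0214, and adjusted p = 0.503 with an estimated correlation). Aim2, a sensor of DNA, was at -1.72. That call was lost without PBS male-1 (0.112), PBS female-2 (0.0748), Bacteria male-1 (0.1804) and Bacteria female-1 (0.0713). Of 7 NF-kB targets 3 fell, 3 also adjusted over the list alone (adjusted p = 0.0439, and adjusted p = 0.757 with an estimated correlation), a call lost without Bacteria female-1 (0.14) and Bacteria female-2 (0.930).

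All 13 genes of mitochondrial DNA rose in the retinal ganglion cells captured after bacteria, as did many chaperone genes. The mitochondrial list stood apart from the other genes (camera adjusted p = 1.09e-15, and adjusted p = 0.503 with an estimated correlation), with 13 risen also adjusted over the list alone, and mt-Nd5 rose from 180 ± 31.4 to 1489 ± 474 CPM (log2 fold change 3.06, SE 0.261, edgeR adjusted p = 4.33e-07, n = 3 per group). The median percent of mitochondrial UMIs per ganglion cell was 0.991 ± 0.302 in PBS and 5.17 ± 2.36 in Bacteria libraries (exact permutation p = 0.1). Median UMIs per ganglion cell were 2788, 5544 and 5311 in PBS male-1, female-1 and female-2. They were 1940, 2180 and 1801 in Bacteria male-1, female-1 and female-2, from 21, 32 and 61 cells. Median genes were 1625.5, 2648 and 2508 in PBS and 906, 1339.5 and 672 in Bacteria libraries. A response of these cells was not told apart from their lower depth or their condition. Of 18 heat shock genes 12 rose, 12 also adjusted over the list alone (adjusted p = 3.48e-11, and adjusted p = 0.183 with an estimated correlation). Hsph1 rose by 3.79 and Hspa1a from 0 to 328 ± 140 CPM, at least 377-fold higher in these counts. The ganglion cell sums of PBS male-1, female-1 and female-2 held 3, 4 and 2 genes at 0 where the lowest Bacteria level would give at least 20 UMIs. The 0 of Hspa1a may therefore not be its expression. Mt2, a metallothionein, rose by 7.003, and Lmo3, a transcription cofactor (chromosome 6, 138362918 to 138581968), went from 108 ± 23.5 CPM to 0, at least 11.6-fold lower. Of 21 glycolysis genes 5 rose, 9 adjusted over the list alone (adjusted p = 1.70e-05, and adjusted p = 0.503 with an estimated correlation). Of 7 immediate early genes 5 rose, 5 also adjusted over the list alone (adjusted p = 0.00553, and adjusted p = 0.503 with an estimated correlation), a call lost without Bacteria female-1 (0.196), without Bacteria female-2 (0.399) and after free RNA was subtracted (0.431). Of 25 ribosomal protein genes 2 rose, 4 adjusted over the list alone (adjusted p = 0.000984, and adjusted p = 0.753 with an estimated correlation), a call lost without PBS female-2 (0.297). In all, 332 genes rose and 467 fell among 8790 tested, 250 and 430 at least 2-fold, in 632 PBS and 114 Bacteria cells with 87570 to 1406589 UMIs per library. The groups' libraries did not overlap for 29.9% of genes, where chance gives 10%. The 799 changed genes became 370, 299 and 358 without PBS male-1, female-1 and female-2, and 472 without Bacteria female-2.

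**Figure D3:**
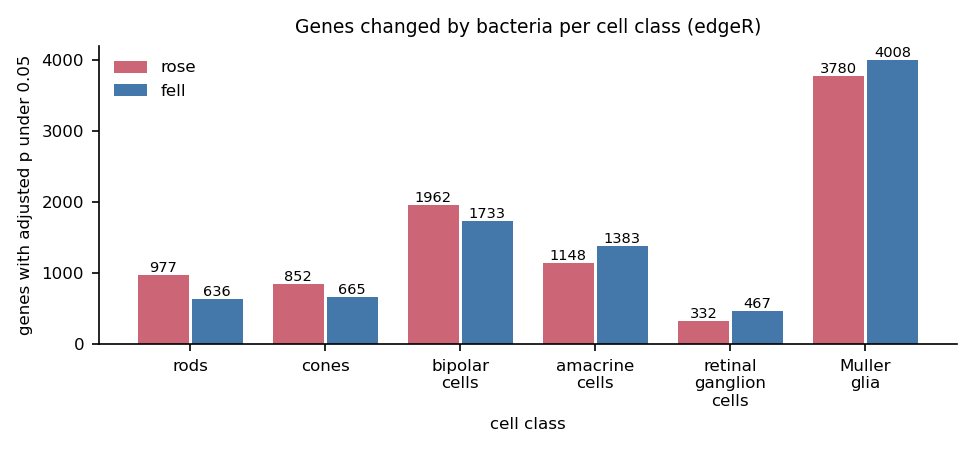
Number of genes with an edgeR adjusted p under 0.05 per tested class, on a linear axis from 0, with genes that rose after bacteria in red and genes that fell in blue. Muller glia have 3780 risen and 4008 fallen genes, and retinal ganglion cells 332 and 467.

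Genes above 100 CPM in neutrophils made up 15.4% of risen and 8.76% of tested genes in cones, 16.0% and 8.95% in retinal ganglion cells, 12.3% and 6.74% in amacrine cells, 14.2% and 7.91% in Muller glia, 9.48% and 6.69% in bipolar cells and 7.06% and 6.99% in rods, and no test was made of these shares.

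Of the 33 lists, 27 had at least 5 tested members in some class. The lists of neutrophil, monocyte and macrophage, lymphocyte, homeostatic microglia, lens crystallin and class II genes had fewer in every tested class, and lists of complement, cholesterol synthesis, endothelial barrier and photoreceptor transcription factor genes were called in none. In all, 51 of 123 tests of lists and classes were called, and 0 with an estimated correlation, where the smallest adjusted p was 0.183. By fry in one direction, which does not compare a list with other genes, 34 of the 51 kept their call and 17 did not. These were red blood cell, rod phototransduction, oxidative phosphorylation, glycolysis, heat shock and ribosomal protein genes in rods (adjusted p 0.0546 to 0.334), rod phototransduction, mitochondrial DNA and ribosomal protein genes in cones (0.0517 to 0.228), and disease-associated microglia and ribosomal protein genes in bipolar cells (0.0538 and 0.130). In amacrine cells they were NF-kB targets, mitochondrial DNA, glycolysis and heat shock genes (0.0688 to 0.462), in retinal ganglion cells ribosomal protein genes (0.339) and in Muller glia class I antigen presentation (0.176). In each called list the mean, the median and the test had the same sign. In some uncalled ones they did not, such as NF-kB targets in rods, with a median log2 fold change of -0.38 and a mean of 1.42.

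Stat3, Hsph1, Hspa1a, Hspa1b, Prkab2, Egln1, Rock2 and Gadd45g rose in all 6 tested classes, and the predicted genes Gm12709 and Gm19522 fell in all 6. Prkab2 is a subunit of the energy sensor AMPK, and Egln1 is the oxygen sensor that marks hypoxia factors for degradation. The log2 fold change of Stat3 (chromosome 11, 100885098 to 100939540) lay between 2.30 in amacrine cells and 3.13 in rods, where it was 3.81 without PBS female-2. Hsph1 (chromosome 5, 149614287 to 149636376) lay between 2.25 and 3.96, Prkab2 between 0.93 and 2.47, Egln1 between 0.79 and 2.16, and Rock2, a kinase of the cytoskeleton, between 0.71 and 2.31. Among the 6642 genes tested in every class, independent lists of the same sizes would share 0.00919 risen and 0.00137 fallen genes. These 10 genes were named after their values were seen, and part of the excess may come from the libraries that all classes share.

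**Figure D4:**
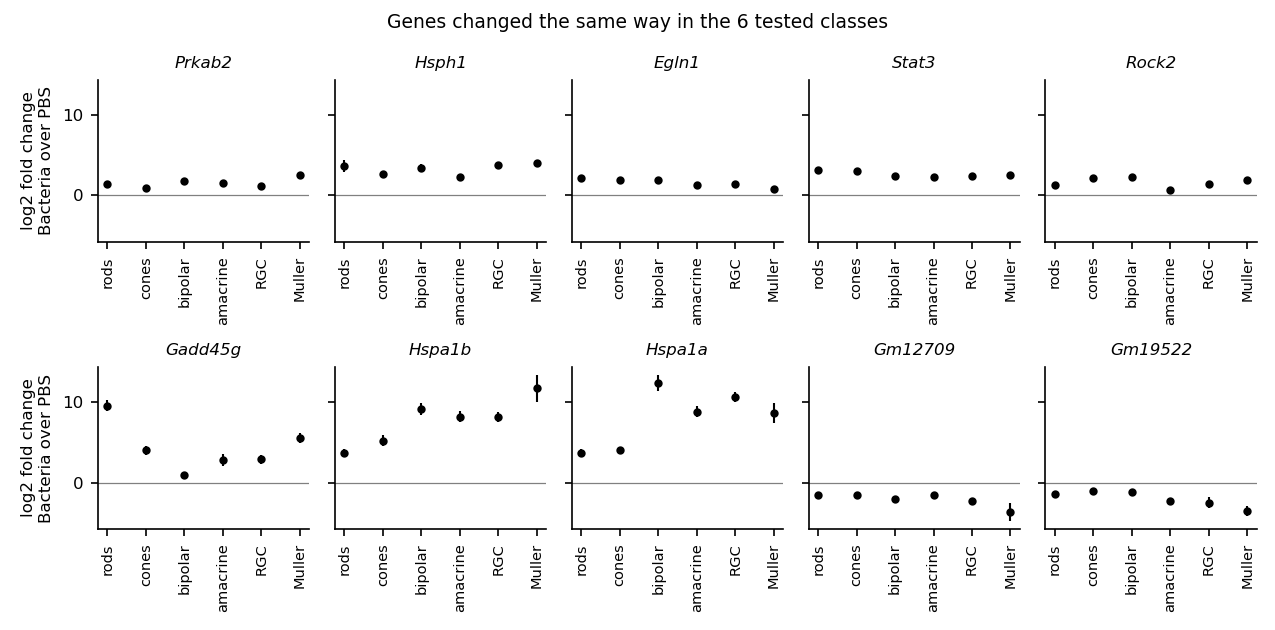
Log2 fold change (Bacteria over PBS) with its standard error in 6 cell classes for the 10 genes that changed the same way in each, with a grey line at 0. Stat3 lies between 2.30 and 3.13, and Gm12709 between -3.64 and -1.49.

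The response of Muller glia differed from that of rods in more genes than the response of any neuronal class did. The interaction of class and treatment differed for 4444 of 14658 genes in Muller glia, 1915 with a higher and 2529 with a lower log2 fold change than in rods. It differed for 319 of 12508 genes in cones (126 higher, 193 lower), 364 of 14482 in bipolar cells (104 and 260), 333 of 14972 in amacrine cells (68 and 265) and 392 of 13583 in retinal ganglion cells (91 and 301). The genes named next were chosen after their values were seen. Mdm2 rose in Muller glia by 3.85 and was at -0.17 in rods (difference 4.07, SE 0.4998, edgeR adjusted p = 0.00157), and Fabp5 was at 4.96 and -0.75 (difference 5.73). Tnfaip3 rose in Muller glia and fell by 1.92 in rods (difference 10.75, adjusted p = 0.000766). Its fall in rods lost the call without PBS male-1 (0.0763), PBS female-1 (0.0709), PBS female-2 (0.0566) and Bacteria female-1 (0.111). Tnfaip3 is also among the 79 bipolar genes called below for the interaction of sex and treatment. In the rod sums of Bacteria male-1, female-1 and female-2, 3, 3 and 64 genes were at 0 where the lowest PBS level would give at least 20 UMIs. The PBS sums held 33, 71 and 28 such genes by the lowest Bacteria level. The fall of Tnfaip3 in rods may in part not be its expression. Hmgb2, a chromatin protein, rose by 6.64 in bipolar cells and fell by 1.56 in rods (difference 8.21, adjusted p = 0.0203). Its value in bipolar cells was 5.98 without PBS female-1 and 8.39 without PBS female-2. Hsp90aa1 was at 2.27 in amacrine cells and 0.17 in rods (difference 2.13, adjusted p = 0.0290).

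The counts of genes that differed from rods rested on single libraries in the neuronal classes. Without PBS male-1, female-1 and female-2, then Bacteria male-1, female-1 and female-2, cones gave 194, 102, 155, 719, 176 and 212 genes and bipolar cells 8, 1, 20, 1046, 18 and 118. Amacrine cells gave 42, 0 and 4 without the PBS libraries in that order, 817 without Bacteria male-1 and 1 without Bacteria female-1. Retinal ganglion cells gave 247, 141 and 184 without the PBS libraries, 654 without Bacteria male-1 and 42 without Bacteria female-1. Muller glia gave 2487, 2108 and 2341 without the PBS libraries and 2773 without Bacteria female-1.

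The interaction of sex and treatment called 79 of 12929 genes in bipolar cells, 77 of them with a larger fold change in the male libraries. Each group holds 1 male library, so this compares these libraries and not the sexes. Actg1, a cytoskeletal actin named after its values were seen, had the smallest p, with a log2 difference of 3.57 (male minus female, edgeR adjusted p = 0.0266). In rods, cones, amacrine cells, retinal ganglion cells and Muller glia 0 genes were called by edgeR, with 685, 511, 2200, 480 and 1120 at an unadjusted p under 0.05 (2136 in bipolar cells). Without the low-count filter 97, 57, 666, 6 and 28 genes were called in those classes and 1045 in bipolar cells.

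Muller glia held fewer genes and UMIs per cell after bacteria, and macrophages and microglia held more UMIs. In Muller glia the median of genes per cell was 3607 ± 477 in PBS and 1762 ± 171 in Bacteria libraries, with median UMIs of 8997 ± 1832 and 4816 ± 1168 (n = 3 each, exact permutation p = 0.1 for both). With each cell thinned to 1000 UMIs the medians were 733 ± 7 and 607 ± 25.7 genes (exact permutation p = 0.1), which left out 14, 19 and 20 shallower cells in PBS and 9, 42 and 50 in Bacteria libraries. In macrophages and microglia median UMIs were 1269 ± 276 and 9522 ± 1217 (exact permutation p = 0.1), from 9, 18 and 33 cells in the PBS and 3, 28 and 47 in the Bacteria libraries. Over all cells median UMIs were 1358 ± 36.1 and 1871 ± 375, and median genes 787 ± 18.0 and 938 ± 83.1 (exact permutation p = 0.1 for both). The median mitochondrial percent was 0.922 ± 0.210 and 1.04 ± 1.19 (exact permutation p = 1), and its difference turned to -0.559 without Bacteria male-1.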

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

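The tests of neutrophil RNA and of sex below, the test of free RNA in macrophages, and the counts over other splits were chosen after the results were seen. The test at equal UMIs in bipolar cells was chosen after its 79 genes had been called, and its prediction was written before its outcome. In bipolar cells the interaction of sex and treatment called 79 genes. Of these, 77 had a larger fold change in the male libraries, of which each group holds 1. With every library thinned to 2887560 UMIs, the sum of Bacteria male-1, 124 were called, which argues against deeper sums of other libraries as the source. Depth per cell was not evened out. Median UMIs per bipolar cell were 7163, 1744 and 3321.5 in Bacteria male-1, female-1 and female-2. They were 2846, 3971 and 3185 in the PBS libraries in that order. Median mitochondrial percents were 2.38, 1.16 and 1.24 in the Bacteria and 1.06, 1.40 and 1.21 in the PBS libraries. Whether these differences between cells gave the calls was not tested. In 71 of the 79 genes both female Bacteria libraries lay below every PBS library, and in 30 the male one lay above every PBS library. Their median level in neutrophils was 119 CPM, at percentile 100 of random sets of tested genes (median 9.30), so a candidate explanation is that RNA of neutrophils, more common in the female Bacteria libraries, was subtracted too strongly before deposit. No source used here states such a step. Sex cannot be told apart from a single library, because each group holds 1 male library.

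In macrophages and microglia, markers of monocytes and macrophages were at 85.1, 373 and 1593 CPM in PBS and 3662, 12040 and 9135 CPM in Bacteria male-1, female-1 and female-2 (exact permutation p = 0.1), where the class had 3, 28 and 47 cells. Neutrophil markers were at 167 ± 123 CPM in PBS (n = 3) and at 14898, 796 and 4386 CPM in the same Bacteria libraries (exact permutation p = 0.1). Free RNA of neutrophils as the source of the monocyte markers is argued against by their level, which was 6.57, 30.2 and 21.4 times that of the neutrophils of Bacteria male-1, female-1 and female-2. Monocytes that entered the retina and microglia that changed their genes may each give this pattern, and no test here parts them.

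The difference itself was tested for the response of each class against that of rods. It passed for 319 genes in cones, 364 in bipolar cells, 333 in amacrine cells, 392 in retinal ganglion cells and 4444 in Muller glia. For each of these 5 counts 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, and the highest of the other splits gave 69, 0, 0, 5 and 0. The numbers of changed genes were likewise reached by 1 of 10 splits in each class, with 1613 in rods, 1517 in cones, 3695 in bipolar cells, 2531 in amacrine cells, 799 in retinal ganglion cells and 7788 in Muller glia, and 0 in every other split of each. The 10 genes changed the same way in all 6 classes were matched by 1 split, the real one, against 0 in the others. Called lists, adjusted within a class for this count, numbered 12, 10, 6, 4, 5 and 13 in rods, cones, bipolar cells, amacrine cells, retinal ganglion cells and Muller glia. The highest of the other splits gave 12, 11, 9, 11, 6 and 17, and 2, 2, 5, 8, 4 and 7 of the 10 splits gave as many lists as the real one. These 10 splits are too few for a share under 0.05. Every split other than the real one also mixes both treatments within each group. A treatment effect then widens the spread within groups and lowers the number of genes called. Counts of genes in those splits therefore do not show how many calls arise without a treatment effect.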

How the results depend on the processing

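The settings that take rods or Muller glia by cluster, subtract free RNA from cones by Muller glia genes, thin the sums or take neurons alone as the total were chosen after seeing the data. The counts of called genes that leave out genes at 0 were also chosen then. Among tests of lists under other settings 668 kept direction and side of the threshold, 114 kept direction alone and 3 reversed. For named genes these were 4450, 296 and 11, and 92 passed newly. With sex added 2587 genes changed in rods. Against a fold of 1.5, 753 changed in rods, 459 in cones, 789 in bipolar cells, 658 in amacrine cells and 287 in retinal ganglion cells. Female libraries alone gave 578 in cones and 350 in retinal ganglion cells, and equal cells per library gave 937 in amacrine cells and 181 in retinal ganglion cells. With free RNA subtracted 568 changed in cones, and 109 and 189 differed from rods in cones and bipolar cells. Rods of clusters 0, 1, 2 and 3 gave 2678, 3614, 803 and 903 changed genes, and clusters 0 and 3 gave 5 and 7 called lists. With Muller glia in place of rods 4382, 5336, 5551 and 3908 genes differed in cones, bipolar cells, amacrine cells and retinal ganglion cells. Without the low-count filter 97, 57, 1045, 666, 6 and 28 genes were called for the interaction of sex and treatment in rods, cones, bipolar cells, amacrine cells, retinal ganglion cells and Muller glia, and with sums thinned 124 were in bipolar cells. An estimated correlation gave 0 lists in each class by camera. By fry, 6 lists moved one way in rods and 3 in amacrine cells, and 20, 12, 9 and 22 moved in either direction in bipolar cells, amacrine cells, retinal ganglion cells and Muller glia. The causes were not tested.

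Some values reversed. The log2 fold change of the share of rods was 0.033 with neurons alone as the total, and that of bipolar cells -0.094 in stricter cells. In rods, stricter cells gave Hbb-bt 0.31 and Hbb-bs 0.21. Cluster 0 alone gave Ndufa4 1.00, Rpl41 1.14 and Ndufv1 1.49, and turned the oxidative phosphorylation list without a call (adjusted p = 0.273). Cluster 1 alone gave Rplp0 1.42, Ndufa4 0.21, Rpl41 0.47, Atp5o 1.47 and Ndufv1 1.24, of which Rplp0, Atp5o and Ndufv1 passed there (adjusted p = 0.0346, 0.0348 and 0.0248). It turned that list, which passed higher there (adjusted p = 0.000384) and lower in the class, and the ribosomal one without a call (adjusted p = 0.322). Otx2 in cones was -0.070 with free RNA subtracted. The cause was not tested.

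Leaving out each library in turn gave 543 to 3184 changed genes in rods, 761 to 1553 in cones, 1408 to 5831 in bipolar cells, 762 to 4372 in amacrine cells, 299 to 759 in retinal ganglion cells and 6636 to 8507 in Muller glia. Genes that differed from rods numbered 102 to 719, 1 to 1046, 0 to 817, 42 to 654 and 2108 to 4778 in the last 5 classes in that order. The log2 fold change of shares ran from 11.85 to 13.31 in neutrophils, 0.87 to 1.58 in Muller glia, -1.27 to -0.76 in amacrine cells, 0.32 to 1.36 in vascular cells, 0.04 to 1.77 in astrocytes, 0.15 to 1.23 in macrophages and microglia, -1.30 to -0.41 in horizontal cells, -0.20 to 0.21 in bipolar cells and -2.29 to -1.86 in retinal ganglion cells. The mitochondrial percent difference ran from -0.559 to 0.522, and called lists from 10 to 14 in rods, 9 to 12 in cones, 6 to 8 in bipolar cells, 3 to 8 in amacrine cells, 4 to 7 in retinal ganglion cells and 12 to 14 in Muller glia.

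With the replicate number as a block 2882 genes changed in rods, 1424 in cones, 2535 in bipolar cells, 753 in amacrine cells, 533 in retinal ganglion cells and 6983 in Muller glia. The numbers did not pair the libraries: the correlations of same-numbered libraries were not all over 0.1 in any class (in rods 0.337, -0.125 and 0.190), and 1, 0, 0, 0, 2 and 2 of 3 libraries correlated best with their own number. Retinal ganglion cells could not be tested at 50 cells or more per library, since too few libraries were left. Barcodes outside the kept cells and clusters at another resolution were not run. Retinal ganglion cells rested on 87570 UMIs in their smallest library.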

Other observations

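The tests of free RNA and of genes per cell in Muller glia and the small cell classes, with a minimum of 5 cells per library, were chosen after the results were seen. The 2 tests of hypoxia targets were chosen after rises had been noticed, and their predictions were written before their outcomes. Genes of resting microglia, the resident macrophages of the retina, fell in the macrophage and microglia class, where 471 genes rose and 331 fell among 1680 tested (3 PBS and 2 Bacteria libraries, edgeR). All 13 tested homeostatic microglia genes fell, and the sum of microglia markers was 21913 ± 3751 CPM in PBS and 599 ± 252 CPM in Bacteria libraries (n = 3 each, exact permutation p = 0.1), of which male-1 held 3 cells of the class. Of 16 NF-kB targets 15 rose, and of 17 glycolysis genes 16 rose and 1 fell. Of 11 monocyte and macrophage markers 9 rose and 1 fell.

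Vascular cells had 404 risen and 405 fallen genes among 1446 tested, astrocytes 212 and 236 among 1653, and horizontal cells 345 and 393 among 3520. In vascular cells all 15 tested NF-kB targets rose, all 14 nuclear oxidative phosphorylation genes fell, and 9 of 12 endothelial barrier genes fell and 1 rose. Pericyte and smooth muscle markers there were at 10646 ± 5398 CPM in PBS and 7.27 ± 7.19 CPM in Bacteria libraries (n = 3 each, exact permutation p = 0.1), beside endothelial markers at 8180 ± 2877 and 7831 ± 1568 CPM (exact permutation p = 0.8) and neutrophil markers at 55.4 ± 21.9 CPM in PBS and 101, 9635 and 856 CPM in Bacteria male-1, female-1 and female-2 (exact permutation p = 0.1), which held 10, 11 and 47 cells of the class. In astrocytes all 11 NF-kB targets rose and 12 of 19 gliosis genes rose and 1 fell. The one that fell was Gfap, the filament protein of astrocytes, at 892, 954 and 3800 CPM in PBS male-1, female-1 and female-2 and 21.8 ± 7.15 CPM in Bacteria libraries (n = 3), while astrocyte markers were at 4590 ± 2366 and 98.9 ± 48.6 CPM (n = 3 each, exact permutation p = 0.1). Muller glia markers there were at 17525 ± 5739 and 4238 ± 238 CPM, and pericyte and smooth muscle markers at 688, 680 and 2056 CPM in the PBS and 224, 13.96 and 27.1 CPM in the Bacteria libraries (exact permutation p = 0.1 for both). The Bacteria libraries held 7, 9 and 69 cells of the astrocyte class, and with these marker levels its name may not hold there. In horizontal cells, fitted on 3 PBS and 2 Bacteria libraries, 23 of 25 ribosomal protein genes and 9 of 14 heat shock genes rose. Their median mitochondrial percent was 0.947, 0.516 and 0.839 in PBS male-1, female-1 and female-2. It was 3.33 and 3.16 in Bacteria female-1 and female-2.

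Muller glia held fewer genes per cell after bacteria also with each cell thinned to 1000 UMIs. The highest Bacteria median was then 634 genes and the lowest PBS median 726, which argues against fewer UMIs per cell as the whole source. Of 1463 genes at least 4 times more abundant in a neuronal class 25.8% fell in Muller glia, against 56.4% of 798 genes at least 4 times more abundant in Muller glia. Both sets were picked by levels in PBS Muller glia, which also enter the fold change. This contrast therefore cannot decide whether less free RNA of neurons gave the falls. A change of the glia themselves may remain as a hypothesis, and it was not tested.

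A hypothesis from the rises seen in rods and bipolar cells is a wider response of hypoxia targets. A list of 24 further targets was set against random lists of tested genes. Its mean log2 fold change was at percentile 99.96 in rods, where 11 of 18 tested targets rose and 1 fell, and at percentile 99.81 in bipolar cells, where 14 of 21 rose and 1 fell. These values are consistent with the hypothesis, but with an estimated correlation camera gave p = 0.108 and p = 0.0673, and exact permutation tests of the mean gave p = 0.1 in both. The percentile was 99.81 in cones, 99.97 in amacrine cells, 99.9 in retinal ganglion cells and 82.66 in Muller glia. In these classes camera with an estimated correlation gave p = 0.333, 0.0688, 0.128 and 0.784 in that order. Exact permutation tests gave p = 0.3, 0.1, 0.1 and 0.4.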
